A study of Taeniopygia guttata and Gallus gallus with 22 samples.

How the data were processed

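Gonadal cultures from zebra finch and chicken embryos were profiled by RNA sequencing in 22 libraries. Of these, 12 were bulk libraries of non-adherent zebra finch cells spanning day in vitro 1 (DIV1) to DIV10, with 1 library per day up to DIV8 and 2 each at DIV9 and DIV10. The other 10 were droplet single-cell libraries, 5 per species. In each species they held non-adherent cells at DIV3 (2 libraries, culture batches A and B), adherent cells at DIV3 and non-adherent cells at DIV6 (1 each, batch B). Zebra finch added adherent cells at DIV6 (batch B), and chicken added an established male White Leghorn line of primordial germ cells (PGCs, the embryonic precursors of eggs and sperm) at DIV150, grown on mitotically inactivated mouse fibroblasts. Per the labels, primary cultures were started from pools of unsexed embryos and dead cells and debris were removed by DAPI sorting. The batch B fractions and days came from the same pool, with part of the pellets taken at DIV3 and the rest cultured on to DIV6. Neither a pool nor a library is an independent animal, so p-values of single genes measure the spread between these samples. The line was derived from gonads of single embryos, frozen, thawed and passed through dead-cell removal.

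The deposited values are counts: whole-number UMI counts per gene and barcode for the single-cell libraries, and whole-number read counts per gene for the bulk libraries, none of them normalised. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 5.1.0 and R 4.4.1 for the single-cell data, the mouse build mm10 for the feeder cells, and HISAT2 2.2.1 and DESeq2 for the bulk data. The bird genome builds and the bulk read counter are not given in the sources used here, so no gene positions are printed. The bulk and the zebra finch single-cell tables hold the same 21762 features, of which 4 are named as copies on the germline-restricted chromosome (GRC), a chromosome that songbirds keep in germ cells and lose from somatic cells. Of 8238 zebra finch locus identifiers, 526 were given a symbol from the reference table supplied. The chicken tables hold 24180 features. The barcodes are those called as cells by the authors.

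Every barcode with at least 500 detected genes was taken into clustering, run per species over its 5 libraries. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours fed a shared-neighbour graph split by the Leiden method at resolution 1. Genes of the GRC paralogue list, the GRC features and mitochondrial genes were left out of the genes used for clustering. Doublets were scored against simulated pairs of cells and removed at a rate of 0.8% per 1000 cells. A cluster took the class whose markers were on in the largest share, with at least 3 of them on. A marker was on at 20 CPM (count share scaled for library size) or more, in at least 10% of the cluster's cells, and at no less than 25% of its level in the highest cluster. A cluster stayed unnamed when it held fewer than 10 cells, when its median UMI count was under 1000, when its median mitochondrial share was above 25%, or when its 10 leading genes held more markers of another class. It also stayed unnamed when its cells had under 1/3 of the library's median UMIs and none of its 10 leading genes was a marker of its class. Unnamed clusters held 13.0%, 13.1%, 20.6%, 18.0% and 24.5% of cells in zebra finch non-adherent DIV3 replicates 1 and 2, adherent DIV3, non-adherent DIV6 and adherent DIV6, and 85.9%, 52.8%, 27.9%, 23.9% and 17.9% in chicken non-adherent DIV3 replicates 1 and 2, adherent DIV3, non-adherent DIV6 and the line. These naming thresholds were set over several tries after clusters had been looked at, whereas the gene lists, and the comparisons and tests other than those named as added later, were fixed before the data were examined. Cells of the germ-cell class are called germ cells below, which describes their markers and not a lineage test.

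The 12 marker lists were germ cell, coelomic and gonadal surface epithelium, supporting cell, steroidogenic cell, interstitial mesenchyme and fibroblast, smooth muscle and pericyte, endothelium, erythroid, macrophage and leukocyte, thrombocyte, mesonephric and kidney epithelium, and neural crest and glia. The 16 gene lists were germline, pluripotency and PGC identity, meiosis, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, integrated and ER stress, p53 response and apoptosis, immediate early and heat shock, FGF and ERK targets, TGF-beta and BMP targets, WNT targets, extracellular matrix, interferon response, and GRC paralogues. All were written from general knowledge, and a few genes stand in more than 1 list.

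Counts were summed per library and class, so that libraries and not cells were the replicates. Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 after TMM scaling and filterByExpr, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE given with these values is the absolute log2 fold change or slope divided by the square root of F. It is derived from the test and adds no evidence beside its p. The bulk model was a slope on day in vitro over 12 libraries. The zebra finch single-cell models had fraction and day as additive terms over 5 libraries, once for germ cells and once for all other cells. No single somatic class had the required 50 cells in each of the 5 libraries. Mesenchyme-like cells numbered 45 in non-adherent DIV3 replicate 2. Every cell outside the germ-cell class was therefore summed, unnamed clusters included. The species model had species and day over the 6 non-adherent short-term libraries and used genes with an identical symbol in both annotations. A model of the day change between species was added after the data had been seen. GRC paralogues were tested between germ cells and all other cells with library as a block, in 5 zebra finch and 4 chicken libraries.

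Lists were tested with camera of limma 3.58.1, a competitive test that compares a list with all other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. With that preset, a list p rests mainly on the spread between genes and not on the spread between libraries. Adjustment was over the 28 lists, and camera with an estimated correlation and fry were run beside it. Values called adjusted over the list alone use only the list's own genes. Chicken groups with 1 library had no test. They are given as log2 ratios of CPM (pseudocount 1) against the mean of the 2 DIV3 non-adherent libraries, with the median of each list ranked among 10000 random lists matched on expression in 20 bins. Shares of cells have exact Clopper-Pearson intervals at 95%, and single CPM values have Poisson intervals. Folds against a count of 0 use a floor of 3 counts per library. Intervals and floors cover counting error only. The bulk cDNA was amplified by PCR, and its reads are not independent molecules. For shares of cells with a UMI of a gene, cells were thinned to 5000 UMIs, and cells with fewer were left out.

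Genes were named by a fixed rule. For each tested comparison these were up to 2 members of each list with the smallest adjusted p past 0.05, and the 5 that rose and the 5 that fell most among genes past 0.05 with a mean log2 CPM of at least 3, symbols only. Untested comparisons drew on the 10 highest and the 10 lowest log2 ratios among genes with at least 50 CPM and 100 UMIs whose value lay outside the range of both DIV3 non-adherent libraries. DAZL, DDX4, NANOG and POU5F3 are given in every comparison where the annotation has them. No zebra finch feature carries the symbol NANOG or POU5F3, so neither was analysed here in that species.

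Depth set the precision as follows. Bulk libraries held 53518544 to 66937133 reads, zebra finch single-cell libraries 109047279 to 146762273 UMIs and chicken single-cell libraries 36571182 to 136640168 UMIs. On simulated data with 200 changed genes, the germ-cell day test recovered 59% of genes changed by 1 on the log2 scale and 87% changed by 2, with 5.45% of calls false. The germ-cell fraction test recovered 51% and 72%, the species test 55% and 90%, the somatic fraction test 14% and 81%, the somatic day test 21% and 73%, and the day change between species 5% and 51%. False shares among these calls ran from 4.35% to 13.4%. The bulk slope test recovered 54% of genes changed by 0.3 per day and 3% of those changed by 0.1. In the real data 8176 genes passed in the species fit, 4821 in the germ-cell day fit and 5205 in the bulk fit. These are many more than the 200 simulated, so recovery there may differ from these rates. Lists of unchanged genes were drawn from the same simulated data, which also held the changed genes. Of these lists fry called 37% in the germ-cell fraction design, and its calls are given only as an alternative.

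The alternatives tried were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom, another filter on low counts, a minimum of 1000 genes per cell, doublets kept, Leiden resolution 0.5, germ cells chosen by DDX4 and DAZL UMIs, replicate and batch blocks, other forms of the day term, and each library left out in turn. Added after the data had been seen were a crossed replicate block, a leukocyte covariate in the bulk model, germ-cell sums after subtraction of the other cells' profile, somatic sums over named classes, the alternatives for the day change between species and those for lists in the single-cell comparisons. Mouse cells in the DIV150 library were counted as barcodes with at least 500 mouse genes and most of their UMIs mouse. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3. No RNA velocity, splicing or read-level measure was possible from counts, and these were not analysed here.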

Results

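Gonadal cells of zebra finch and chicken embryos were cultured and profiled as bulk and as single-cell RNA libraries. The questions the design addresses are how the non-adherent zebra finch cells change over 10 days in vitro, which cells stay in suspension and which attach, how germ cells of the 2 species compare under short-term culture, and how an established chicken germ-cell line compares with chicken germ cells at DIV3. The 12 bulk libraries held 53518544 to 66937133 reads and detected 16166 (DIV8) to 20048 (DIV9 replicate 1) genes. The single-cell libraries held 5056 to 9177 barcodes in zebra finch and 3995 to 19234 in chicken, of which 4846 to 8213 and 3865 to 8858 cells were kept. Chicken non-adherent DIV3 replicate 2 was the library with the most barcodes under 500 genes, 77.6%. Germ cells numbered 3400, 3478 and 6306 in zebra finch non-adherent DIV3 replicates 1 and 2 and DIV6, and 90 and 81 in adherent DIV3 and DIV6. In chicken they numbered 230, 364 and 828 in the corresponding non-adherent libraries, 54 in adherent DIV3 and 7270 in the line. Median UMIs per germ cell ran from 14414 to 24612 in zebra finch and from 15136 (line) to 85935.5 (DIV3 replicate 2) in chicken.

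Zebra finch germ cells were a large share of the suspended cells and a small share of the adherent cells. Shares within a fraction do not show what portion of all germ cells attached. They made up 65.1% (95% Clopper-Pearson interval 63.8 to 66.4) and 64.3% (63.0 to 65.5) of non-adherent cells at DIV3 and 76.8% (75.8 to 77.7) at DIV6. In the adherent libraries they made up 1.86% (1.5 to 2.28) at DIV3 and 1.22% (0.970 to 1.51) at DIV6. Macrophage-like cells took 20.4% and 21.3% of non-adherent cells at DIV3 and 3.86% at DIV6, against 0.743% and 0.512% of adherent cells. The adherent cells were mostly mesenchyme-like (40.5% at DIV3, 73.2% at DIV6) and coelomic-epithelium-like (36.3% and 0.558%), classes that held 0.958% or less and 0.230% or less of non-adherent DIV3 cells. At Leiden resolution 0.5 the adherent DIV3 cells were 75.3% coelomic-epithelium-like and 1.07% mesenchyme-like, and with at least 1000 genes per cell the coelomic share at adherent DIV6 was 13.2%. The division between these classes depends on the clustering. Erythroid cells were 0.268% and 0.277% of non-adherent DIV3 cells and 0 of 4846 adherent DIV3 cells (interval up to 0.0761%). In zebra finch no single cluster held the germ cells, and the largest germ cluster of a library took between 16.7% of them (non-adherent DIV6, cluster 6) and 46.9% (adherent DIV6, cluster 12). Clusters also differed between libraries. Cluster 14 held 1, 6 and 888 germ cells and cluster 22 held 1, 0 and 611 in non-adherent DIV3 replicates 1 and 2 and DIV6, and clusters 13, 15, 19 and 23 came mostly from DIV3 replicate 2 (855, 816, 631 and 461 cells). Comparisons of days and of fractions therefore sum germ cells of different clusters.

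Chicken non-adherent cultures held fewer germ cells, and more erythroid cells at DIV3, than those of zebra finch. Macrophage-like cells were fewer at DIV3 (0.154% and 2.33%) and more at DIV6 (17.72%, against 3.86% in zebra finch). Germ cells made up 3.93% (3.44 to 4.46) and 8.75% (7.91 to 9.65) at DIV3, 19.2% (18.1 to 20.4) at DIV6 and 1.40% (1.05 to 1.82) of adherent cells at DIV3. Called by DDX4 and DAZL UMIs they made up 17.95% and 21.68% of non-adherent cells at DIV3 and 27.73% at DIV6. With at least 1000 genes per cell the non-adherent shares were 15.44%, 15.89% and 32.37%. The size of the rise to DIV6 depends on this choice. Erythroid cells made up 3.11% and 16.2% at DIV3, 20.5% at DIV6 and 0.362% of adherent cells, and smooth-muscle-like cells 60.0% of adherent cells. With at least 1000 genes per cell the erythroid shares were 8.45% and 27.9% at DIV3 and 2.23% at DIV6. Their order over days depends on that minimum. In the line, germ cells made up 82.1% (81.3 to 82.9) and no cell was called erythroid, macrophage-like or mesenchyme-like (intervals up to 0.0416% each). Chicken germ cells came from clusters 13 (54.4%) and 19 (45.05%) in non-adherent DIV3 replicate 2, from the same clusters in adherent DIV3 (50% each) and DIV6 (67.03% and 32.85%), and from clusters 19 (54.35%) and 21 (43.9%) in DIV3 replicate 1. Those of the line came mostly from clusters 1, 2 and 4. Chicken non-adherent DIV3 replicate 1 left 85.9% of its cells in unnamed clusters, and 73.6% of its cells were unnamed with germ-cell markers as the best class, so its share of germ cells is a low one. No test was made on shares, because most groups have 1 library. The differences between fractions stand in both zebra finch days but rest on batch B for every adherent library.

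**Figure D1:**
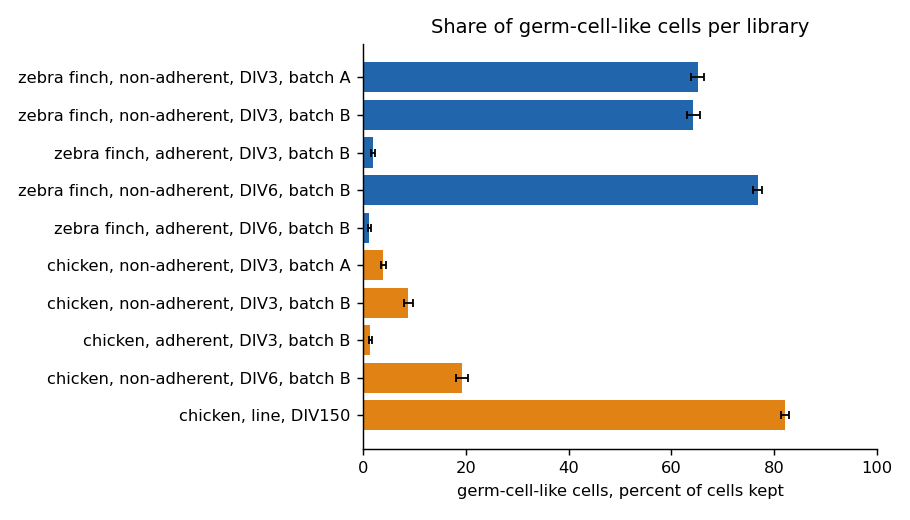
Share of cells kept that were called germ cells (percent, horizontal axis, from 0) in each of the 10 single-cell libraries, with 95% Clopper-Pearson intervals. Zebra finch non-adherent libraries lie at 64.3% to 76.8% and zebra finch adherent libraries at 1.22% to 1.86%.

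Over 10 days in vitro, non-adherent zebra finch cultures gained transcripts of meiosis genes and lost transcripts of cell cycle genes and erythroid markers. TEX12, a component of the synaptonemal complex central element, rose by 1.14 ± 0.11 (SE, n = 12) log2 units per day (adjusted p = 2.57e-05), from 0.0896 CPM at DIV1 to 112 CPM in DIV10 replicate 2. RAD21L1, a meiotic cohesin subunit, rose by 0.77 ± 0.06 per day (adjusted p = 7.48e-06) and TEX11, which acts in meiotic recombination, by 0.42 ± 0.04 (adjusted p = 2.16e-05). Of 21 measured meiosis genes 14 rose and 0 fell, 14 when adjusted over the list alone (camera adjusted p = 3.18e-07; adjusted p = 0.515 with an estimated correlation). Of 28 cell cycle genes 17 fell and 0 rose, 18 over the list alone (camera adjusted p = 7.02e-07; adjusted p = 0.515 with an estimated correlation), among them CCNA2, cyclin A2 (slope -0.32 ± 0.03, adjusted p = 2.00e-05), and CDC20, an activator of the anaphase-promoting complex (-0.42 ± 0.04, adjusted p = 3.72e-05). All 6 erythroid markers fell (camera adjusted p = 0.0261; adjusted p = 0.515 with an estimated correlation). The embryonic globin HBE1 had a slope of -1.14 ± 0.17 (adjusted p = 0.000347) and went from 2876 CPM at DIV1 to 167 at DIV2. HBAD (-1.01 ± 0.17, adjusted p = 0.000753) and HBAA (-0.57 ± 0.12, adjusted p = 0.0034) fell as well, but without the DIV1 library HBAA no longer passed (-0.17, adjusted p = 0.175) and neither did the erythroid list (mean slope -0.27, adjusted p = 0.1). In all, 5205 of 17518 genes passed, 2619 rising and 2586 falling.

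Germ-cell genes did not move as 1 group. DDX4, the germ-cell RNA helicase VASA, had a slope of 0.07 ± 0.04 (adjusted p = 0.194), and DAZL, an RNA-binding protein of germ cells, fell (-0.17 ± 0.05, adjusted p = 0.0123). That call was lost with log2 of day (adjusted p = 0.0808), with the DIV9 and DIV10 replicates summed (adjusted p = 0.0545) and with the leukocyte covariate (adjusted p = 0.0858). Of 19 germline genes 3 rose and 4 fell (camera adjusted p = 0.806), with TDRD7 at 0.20 ± 0.03 (adjusted p = 0.000471) and MAEL, a piRNA pathway factor, at -0.19 ± 0.04 (adjusted p = 0.00144). Of 17 pluripotency and PGC identity genes 1 rose and 5 fell (camera adjusted p = 0.232), among them SALL4 (-0.21 ± 0.02, adjusted p = 8.29e-05) and the receptor KIT (-0.24 ± 0.04, adjusted p = 0.000407). SYCP2L was 1 of the 5 genes that fell most (-0.52 ± 0.03, adjusted p = 1.88e-06), although it is a paralogue of the synaptonemal complex gene SYCP2, and the steepest rises beside TEX12 were MYOT (0.97 ± 0.09), TNNI3 (0.90 ± 0.06), IKZF3 (0.84 ± 0.05) and FBXO47 (0.84 ± 0.09). ADAMTS12 is listed among the steepest falls (-0.68 ± 0.18, adjusted p = 0.0106) because of 154 CPM at DIV2 alone, and without that library its slope was -0.05 (adjusted p = 0.740).

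Some mitochondrial respiration genes fell, and some matrix, leukocyte and kidney genes rose. Of 30 oxidative phosphorylation genes 13 fell and 0 rose, 18 over the list alone (camera adjusted p = 3.93e-05; adjusted p = 0.515 with an estimated correlation), such as NDUFA8 (-0.21 ± 0.04) and SDHB (-0.13 ± 0.03). Of 20 extracellular matrix genes 5 rose (camera adjusted p = 0.0141; adjusted p = 0.569 with an estimated correlation), led by COL6A3 (0.48 ± 0.03, adjusted p = 2.09e-06) and COL6A2 (0.36 ± 0.08). Of 11 macrophage and leukocyte markers 6 rose (camera adjusted p = 0.0343; adjusted p = 0.651 with an estimated correlation), and of 9 mesonephric and kidney markers 4 rose (camera adjusted p = 0.0261; adjusted p = 0.515 with an estimated correlation). At DIV8 the mean log2 CPM was 9.38 for the leukocyte markers and 5.06 for the kidney markers, against at most 7.95 and 2.37 in the other libraries, and the meiosis list stood at 3.14 between 5.10 at DIV7 and 4.79 to 5.27 at DIV9. Without DIV8 the adjusted p was 0.0765 for the matrix, leukocyte and kidney lists and 0.0740 for the erythroid list, and without DIV10 replicate 1 it was 0.0663 for the leukocyte list. Mean slopes without DIV8 were 0.18 for matrix, 0.14 for leukocyte, 0.24 for kidney and -0.49 for erythroid genes, against 0.19, 0.18, 0.26 and -0.51 with it. The calls thus depend on DIV8 more than the slopes do. With the leukocyte marker mean as a covariate the kidney slope fell to 0.09 (adjusted p = 0.413). The matrix (0.14, adjusted p = 0.304) and erythroid (-0.43, adjusted p = 0.0722) lists lost their calls too. The number of genes past the threshold was 7875 without DIV8, of which 5198 were among the 5205.

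**Figure D2:**
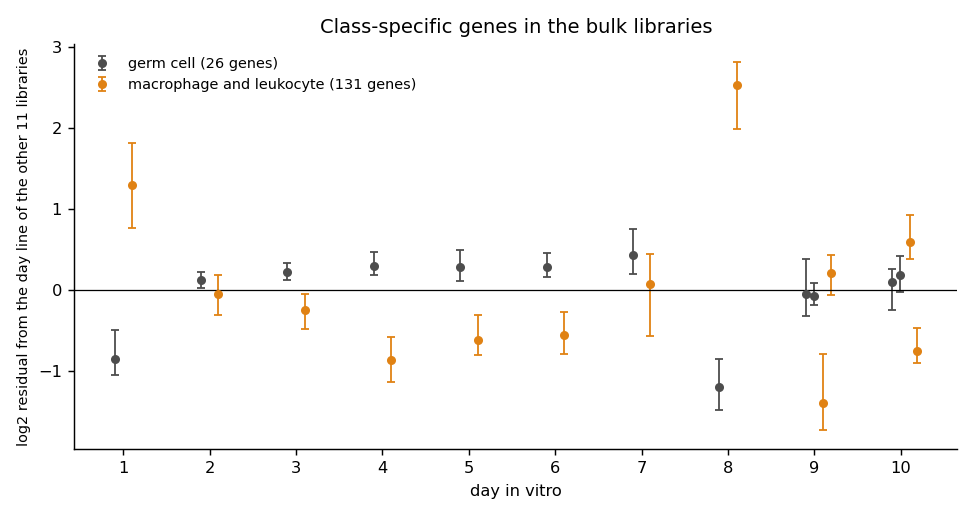
Median residual log2 expression (vertical axis, bars the interquartile range) of each bulk library from the line of day fitted to the other 11 libraries, for 26 germ-cell-specific and 131 macrophage-specific genes of the single-cell data. At DIV8 the macrophage genes lie at 2.54 and the germ-cell genes at -1.19.

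No other list passed camera with day. Members that rose and fell numbered 2 and 0 of 23 for glycolysis and hypoxia, 1 and 5 of 22 for cholesterol synthesis, 3 and 4 of 19 for integrated and ER stress, 5 and 3 of 14 for p53 response and apoptosis, and 1 and 4 of 15 for immediate early and heat shock genes. They numbered 1 and 4 of 14 for FGF and ERK targets, 1 and 1 of 12 for TGF-beta and BMP targets, 0 and 2 of 9 for WNT targets, 0 and 0 of 10 for interferon response and 0 and 3 of 18 for GRC paralogues. Among marker lists, they numbered 1 and 2 of 9 for germ cell, 1 and 2 of 4 for coelomic epithelium, 2 and 0 of 10 for supporting cell, 1 and 0 of 4 for steroidogenic cell, 4 and 0 of 12 for mesenchyme, 1 and 0 of 4 for smooth muscle, 1 and 0 of 10 for endothelium, 1 and 0 of 5 for thrombocyte and 1 and 0 of 5 for neural crest and glia. Single members that passed included PFKM (0.40 ± 0.10) in glycolysis, HERPUD1 (0.25 ± 0.04) in ER stress and MDM2 (0.14 ± 0.03), the ubiquitin ligase that restrains p53. SPRED2 (-0.24 ± 0.04), an inhibitor of ERK signalling, and HSPH1 (-0.28 ± 0.04), a heat shock protein, passed as well. Other members of the ER stress and p53 lists passed in the opposite direction to HERPUD1 and MDM2. All bulk libraries form 1 batch, so there is no other batch to compare.

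**Figure D3:**
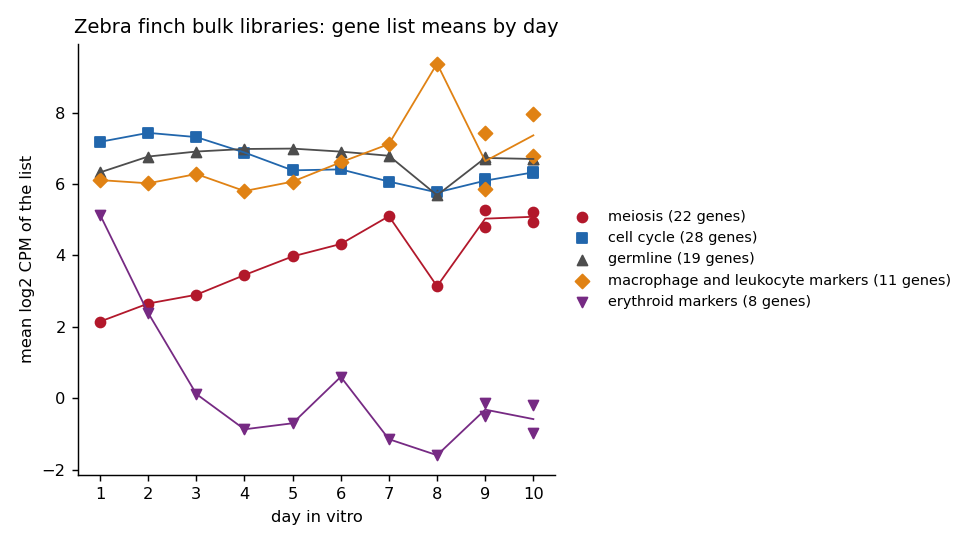
Mean log2 CPM of 5 gene lists (vertical axis) against day in vitro (horizontal axis) in the bulk zebra finch libraries, where points are libraries and lines join day means. The meiosis list goes from 2.15 at DIV1 to 4.94 and 5.23 at DIV10, and at DIV8 it lies at 3.14 while the macrophage list reaches 9.38.

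Within zebra finch germ cells, meiosis genes rose and cell cycle genes fell between DIV3 and DIV6 (2 libraries against 3, fraction as a covariate). STRA8, a retinoic acid target needed for meiotic entry, rose by 3.84 ± 0.23 log2 units (SE; adjusted p = 1.27e-07), from 1.82 to 4.30 CPM in the 3 DIV3 libraries to 53.5 and 70.3 CPM at DIV6. TERB2, which tethers meiotic telomeres to the nuclear envelope, rose by 5.21 ± 0.25 (adjusted p = 1.80e-08), BRDT, a testis bromodomain protein, by 3.89 ± 0.24 (adjusted p = 1.27e-07) and HORMAD2, a meiotic axis protein, by 2.17 ± 0.14 (adjusted p = 1.89e-07). C13H5orf47 (4.82 ± 0.18), CCDC73 (4.2 ± 0.36) and CCDC152 (3.89 ± 0.28) complete the steepest rises. Of 22 meiosis genes 19 rose and 0 fell, 20 over the list alone (camera adjusted p = 2.19e-08; adjusted p = 0.593 with an estimated correlation). Of 28 cell cycle genes 26 fell and 0 rose (camera adjusted p = 3.70e-11; adjusted p = 0.593 with an estimated correlation), with NUSAP1, a spindle protein, at -1.41 ± 0.17 (adjusted p = 4.62e-05) and CCNA2 at -1.47 ± 0.18 (adjusted p = 4.93e-05). In all, 4821 of 16990 genes passed, 2818 higher and 2003 lower at DIV6. Within batch B alone the count was 6358, and without non-adherent DIV6, which holds most of the DIV6 germ cells, it was 872, while both lists stayed past the threshold without any 1 library.

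Single genes of the PGC state fell, while DAZL and DDX4 did not. DAZL and DDX4 are among the markers that named the germ-cell clusters, so cells that had lost such markers could fall outside the sums. KIT fell by 3.22 ± 0.34 (adjusted p = 1.43e-05) and PRDM14, a repressor that acts in PGC specification, by 2.06 ± 0.45 (adjusted p = 0.00378), and of 17 pluripotency and PGC identity genes 1 rose and 9 fell (camera adjusted p = 0.0905). DAZL stood at -0.15 ± 0.16 (adjusted p = 0.520). DDX4 rose by 0.85 ± 0.17 (adjusted p = 0.00179), a call lost without adherent DIV3 (0.69, adjusted p = 0.0535) or non-adherent DIV6 (1.01, adjusted p = 0.0613). ID3, a BMP target, fell by 1.87 ± 0.36 (adjusted p = 0.00147), but not without non-adherent DIV6 (-0.85, adjusted p = 0.342). MTHFD2, an enzyme of mitochondrial folate metabolism, fell by 1.16 ± 0.16 (adjusted p = 0.000114), and PGK1 rose by 1.21 ± 0.18 (adjusted p = 0.00024) in a glycolysis list in which 7 of 23 members rose and 2 fell. Of 18 extracellular matrix genes 8 rose (camera adjusted p = 0.0615), such as COL3A1 (1.71 ± 0.18), which is abundant in mesenchyme. Of 11 macrophage markers 1 rose and 8 fell (camera adjusted p = 0.172), including C1QC (-2.45 ± 0.35, adjusted p = 0.000189), as the share of macrophage-like cells in suspension went from 20.4% and 21.3% to 3.86%. Without non-adherent DIV6 the C1QC call was lost, in a fit where the adherent sums held C1QC counts of only 2 and 0. HBAD and HBE1 are named as falls (-4.13 ± 0.85 and -3.59 ± 1.07), but their levels at DIV3 differed between the libraries, 26.7, 4.29 and 0 CPM for HBAD, and neither passed the DESeq2 Wald test.

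**Figure D4:**
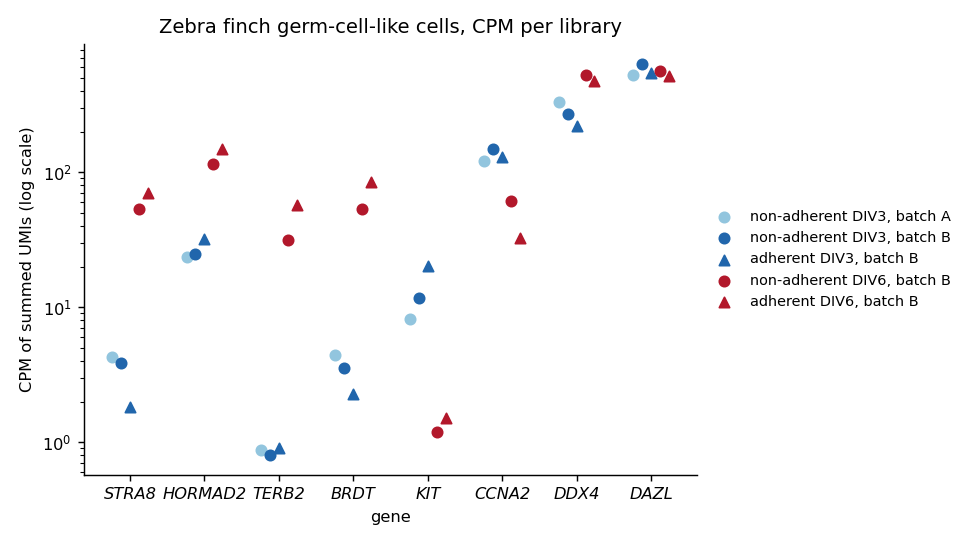
CPM (log scale) of 8 genes summed over zebra finch germ cells in each of 5 libraries. STRA8, HORMAD2, TERB2 and BRDT lie higher in both DIV6 libraries than in all 3 DIV3 libraries, KIT and CCNA2 lie lower, and DAZL ranges from 514 to 640 CPM.

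The few germ cells recovered with the adherent fraction carried more matrix, contractile and mesenchymal transcripts than germ cells in suspension (2 libraries against 3, day as a covariate). TAGLN, an actin-binding protein of smooth muscle, was higher by 6.80 ± 0.19 log2 units (SE; adjusted p = 9.52e-12), at 105 and 125 CPM against 0.768 to 1.21 CPM in the 3 non-adherent libraries. ADAMTSL2 was higher by 7.77 ± 0.30 (adjusted p = 1.75e-10), DCN, the matrix proteoglycan decorin, by 6.51 ± 0.28, ACTA2, smooth muscle actin, by 6.42 ± 0.23, and COL12A1 by 6.02 ± 0.26. Of 18 extracellular matrix genes 14 rose, 15 over the list alone (camera adjusted p = 6.62e-20; adjusted p = 0.221 with an estimated correlation), among them COL3A1 (5.75 ± 0.20) and COL1A2 (4.51 ± 0.16). Of 10 mesenchyme markers 6 rose (camera adjusted p = 7.36e-13; adjusted p = 0.221 with an estimated correlation), as did 3 of 5 smooth muscle markers and 5 of 12 TGF-beta and BMP targets (camera adjusted p = 9.97e-05 for both; adjusted p = 0.587 with an estimated correlation), and 3 of 4 coelomic epithelium markers (camera adjusted p = 0.000264; adjusted p = 0.503 with an estimated correlation). TGFBI (5.26 ± 0.36) and CCN2 (4.97 ± 0.28), secreted proteins induced by TGF-beta, led the TGF-beta list. Macrophage markers went the other way, with 5 of 11 lower (camera adjusted p = 0.00039; adjusted p = 0.587 with an estimated correlation), as macrophage-like cells made up 0.743% or less of adherent cells.

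No difference in germline or meiosis genes was detected between the fractions. Clusters were named germ cells by markers that include DAZL, DDX4 and other members of the germline list. Cells that had lost such markers could fall outside the sums, which limits what this comparison can show for germline genes. None of 19 germline genes (camera adjusted p = 0.180) and none of 22 meiosis genes (camera adjusted p = 0.760) passed, DAZL stood at -0.19 ± 0.16 (adjusted p = 0.756) and DDX4 at -0.41 ± 0.17 (adjusted p = 0.441). SOX2 was lower by edgeR (-0.81 ± 0.18, adjusted p = 0.0171), a call lost without either adherent library or without non-adherent DIV6 (adjusted p = 0.221 to 0.528). NDRG1 (1.81 ± 0.27) and ADM (3.23 ± 0.57), both hypoxia-induced, were higher in a glycolysis and hypoxia list with 2 of 23 members up (camera adjusted p = 0.0218; adjusted p = 0.689 with an estimated correlation). ADM lost its call with germ cells by DDX4 and DAZL UMIs (2.47, adjusted p = 0.112). NDRG1, also higher in the other adherent cells (2.04), stood at 0.58 (adjusted p = 0.897) after subtraction of their profile, and ADM at 5.38 (adjusted p = 0.575). The hypoxia list and the cell cycle list (0 of 28 members past; camera adjusted p = 0.00949, adjusted p = 0.587 with an estimated correlation) lost their calls without adherent DIV3 (adjusted p = 0.134 and 0.101), adherent DIV6 (0.171 and 0.604) or non-adherent DIV6 (0.280 and 0.513), and the hypoxia list also without non-adherent DIV3 replicate 2 (0.129). The hypoxia mean was 0.25, 0.31, 0.32 and 0.25 in these fits against 0.25 over all libraries, while the cell cycle mean was -0.43, -0.17 and -0.16 against -0.32. In all, 433 of 16990 genes passed, 402 higher and 31 lower in adherent germ cells, with 1590 at an unadjusted p under 0.05, 519 by DESeq2, and 671 within batch B alone. The adherent sums rest on 90 and 81 cells, and after subtraction of the other cells' profile 1 gene passed.

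Outside the germ cells, transcripts of extracellular matrix and cholesterol synthesis genes were higher in the adherent fraction and leukocyte markers higher in suspension (2 libraries against 3; 5793 of 14901 genes past, 3051 higher and 2742 lower in adherent cells). COL8A1 was higher by 6.09 ± 0.39 log2 units (SE; adjusted p = 0.000153), RSPO3, a WNT potentiator, by 5.62 ± 0.39, and TNC, the matrix protein tenascin, by 4.39 ± 0.31 (adjusted p = 0.000184), with 17 of 20 extracellular matrix genes up (camera adjusted p = 2.15e-06; adjusted p = 0.610 with an estimated correlation). Of 21 cholesterol synthesis genes 16 rose (camera adjusted p = 0.000128; adjusted p = 0.610 with an estimated correlation), for example FDPS (2.22 ± 0.27, adjusted p = 0.00132). Of 30 oxidative phosphorylation genes 16 rose (camera adjusted p = 0.000136; adjusted p = 0.624 with an estimated correlation), and of 12 TGF-beta and BMP targets 10 rose (camera adjusted p = 6.66e-05; adjusted p = 0.610 with an estimated correlation). All 11 macrophage markers were lower (camera adjusted p = 1.44e-08; adjusted p = 0.610 with an estimated correlation), with CX3CR1, a chemokine receptor of macrophages, at -8.28 ± 0.81 (adjusted p = 0.000642), and HBAD was lower by the most (-10.75 ± 0.53). Germ-cell transcripts were also lower, 14 of 19 germline genes with 1 higher (camera adjusted p = 1.59e-06; adjusted p = 0.610 with an estimated correlation), with DDX4 at -6.62 ± 0.37 (adjusted p = 9.71e-05) and DAZL at -6.69 ± 0.54 (adjusted p = 0.00032). These sums differ in their make-up of classes and include unnamed clusters, and cells unnamed with germ-cell markers as the best class made up 16.1% of non-adherent DIV6 cells and 0.186% of adherent DIV3 cells. Within batch B, without non-adherent DIV3 replicate 1, 3461 genes passed.

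Between DIV3 and DIV6 the other cells showed lower cell cycle expression as a list, and 1 gene passed by itself. This was HBAD of 14901 genes in edgeR, lower at DIV6 with counts of 2 and 0 in the DIV6 libraries, for which no fold is given, and not past without non-adherent DIV6 (adjusted p = 0.106). At an unadjusted p under 0.05 there were 1872 genes, and the DESeq2 Wald test called 390, of which 179 were higher. DDX4 stood at 1.49 ± 0.27 (adjusted p = 0.214) and DAZL at 0.31 ± 0.39 (adjusted p = 0.748). Of 28 cell cycle genes 22 were lower at DIV6 when adjusted over the list alone (camera adjusted p = 7.44e-13; adjusted p = 0.372 with an estimated correlation). The make-up of these sums also differed between days. Among adherent cells, coelomic-epithelium-like cells went from 36.3% to 0.558% and mesenchyme-like cells from 40.5% to 73.2%. A change within a class was not tested apart from this shift. Meiosis genes were higher, 10 of 18 over the list alone (camera adjusted p = 6.35e-08; adjusted p = 0.799 with an estimated correlation), in sums that include cells unnamed with germ-cell markers as the best class, 9.23% and 7.37% of non-adherent DIV3 and 16.1% of non-adherent DIV6 cells. Of 11 macrophage markers 0 passed, and over the list alone 9 were lower and 1 higher (camera adjusted p = 2.67e-05; adjusted p = 0.799 with an estimated correlation). Leaving out adherent DIV3 gave 1260 genes, adherent DIV6 1113 and non-adherent DIV3 replicate 2 84, so the gene count is not stable.

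Germ cells of the 2 species differed in most genes measured in both. In zebra finch, meiosis genes were higher, and in chicken, LIN28A, TFAP2C, SPRY2 and DUSP6 (3 non-adherent libraries each, day as a covariate). The meiotic cohesins REC8 (6.53 ± 0.24 log2 units, SE) and SMC1B (4.89 ± 0.22) and MEIOC, which sustains meiotic prophase (5.33 ± 0.19), were higher in zebra finch, as was PLD6, a piRNA biogenesis factor (9.10 ± 0.35, adjusted p = 1.57e-07). LIN28A, an RNA-binding protein of early germ cells, was at -9.69 ± 0.30 (adjusted p = 1.01e-07) and TFAP2C, a PGC transcription factor, at -6.17 ± 0.31, zebra finch relative to chicken. The ERK feedback inhibitors SPRY2 (-4.09 ± 0.19) and DUSP6 (-5.97 ± 0.39) and the WNT antagonist DKK1 (-7.79 ± 0.27) were lower in zebra finch, whereas LEF1, a WNT effector (3.74 ± 0.20), and EGR1, an immediate early gene (7.36 ± 0.46), were higher. DAZL was at -0.99 ± 0.18 (adjusted p = 0.000912) and DDX4 at 0.19 ± 0.29 (adjusted p = 0.568). Of 19 meiosis genes 13 were higher and 1 lower in zebra finch (camera adjusted p = 0.0330; adjusted p = 0.954 with an estimated correlation). No other list passed, among them germline (12 higher and 4 lower of 19; adjusted p = 0.188), pluripotency and PGC identity (3 higher and 11 lower of 17; adjusted p = 0.0614), FGF and ERK targets (4 higher and 8 lower of 14; adjusted p = 0.587) and cell cycle (19 higher and 1 lower of 27; adjusted p = 0.0515). Macrophage markers were higher in zebra finch germ-cell sums for 6 of 10 (adjusted p = 0.188), and macrophage-like cells were 20.4% and 21.3% of zebra finch and 0.154% and 2.33% of chicken DIV3 cells, but 3.86% and 17.72% of DIV6 cells.

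In all, 8176 of 11567 genes with a shared symbol passed, 4234 higher and 3942 lower in zebra finch, and with culture batch as a block 8070. Absence from 1 annotation, or different transcript ends, acts on this comparison as species does and cannot be separated from it. Of the genes past the threshold, 76 had 0 counts in every chicken library and 20 in every zebra finch library. Against a floor of 3 counts per library, PFDN2, a prefoldin subunit, was at least 2590-fold and RNF212, a meiotic crossover factor, at least 555-fold higher in zebra finch, and PAX4 at least 985-fold higher in chicken.

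Songbird germ cells carry the GRC, so genes reported to have GRC copies were compared between germ cells and all other cells. In zebra finch (5 libraries), 10 of 18 GRC paralogues were higher in germ cells and 3 lower (camera p = 0.0307; p = 0.189 with an estimated correlation). PSIP1, a chromatin-binding transcription cofactor, was higher by 2.96 ± 0.42 log2 units (SE; adjusted p = 0.00155), CPEB1, a translation regulator of oocytes, by 3.02 ± 0.66 (adjusted p = 0.0101), ELAVL4 by 2.81 ± 0.87 (adjusted p = 0.0352), TRIM71 by 2.75 ± 0.81 (adjusted p = 0.0300) and the oocyte growth factor BMP15 by 2.27 ± 0.64 (adjusted p = 0.0258). PIM3 (-0.60 ± 0.20), RXRA (-1.16 ± 0.20) and BICC1 (-1.85 ± 0.49) were lower. In mean CPM, however, PIM3 stood at 87.7 in germ cells against 91.0, and its CPM was higher in germ cells in 3 of 5 libraries. Of the 4 features annotated as GRC copies, 3 were higher in germ cells: GRC_TRIM71 (4.75 ± 1.12, adjusted p = 0.0135; 12.2 CPM in germ cells against 0.872 in the others), GRC_NAPA (4.62 ± 1.44, adjusted p = 0.0366) and GRC_ELAVL4 (4.25 ± 1.39, adjusted p = 0.0434). GRC_BICC1 stood at 0.16 ± 0.49 (adjusted p = 0.822). Of the markers used to name the germ-cell clusters, DDX4 stood at 4.03 ± 1.30 (adjusted p = 0.0406) and DAZL at 4.02 ± 1.39 (adjusted p = 0.0513). The other cells include clusters left unnamed with germ-cell markers as the best class, and no fit without them was made. The counts do not show how reads were divided between a GRC copy and its paralogue on another chromosome. In chicken, which has no such chromosome, 6 of 17 were higher and 6 lower over 4 libraries. The list gave a camera p of 0.514, with PSIP1 at 1.72 ± 0.15 (adjusted p = 0.000197), CPEB1 at 2.31 ± 0.49 and TRIM71 at 2.45 ± 0.84 (adjusted p = 0.0410). A direct test of the difference between species gave a camera p of 0.126. Without adherent DIV3 the zebra finch list p was 0.058.

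**Figure D5:**
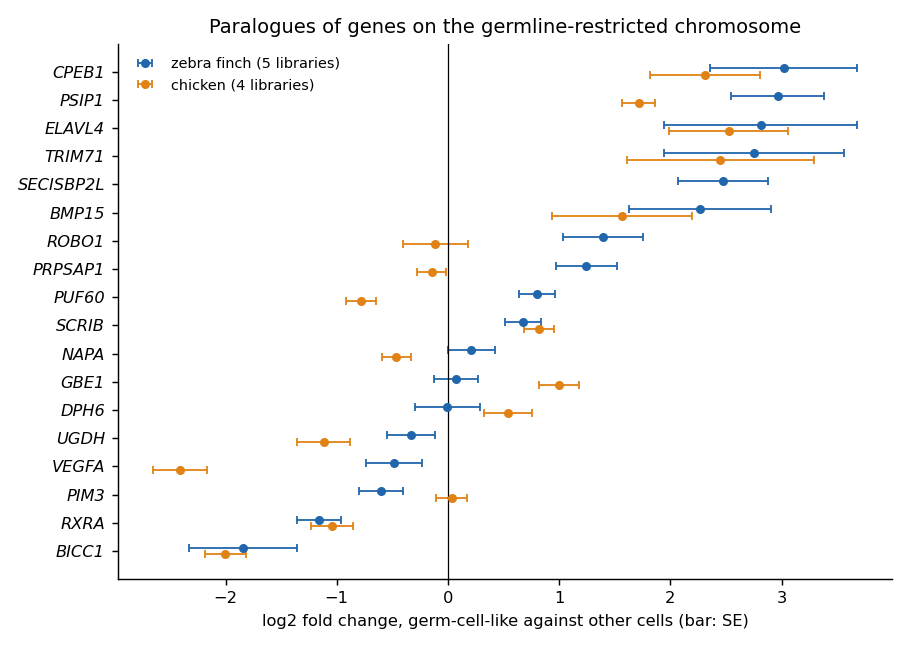
Log2 fold change of each GRC paralogue between germ cells and all other cells (points, with SE bars) in zebra finch (5 libraries) and chicken (4 libraries). PSIP1, CPEB1, ELAVL4 and TRIM71 lie above 0 in both species, and BICC1 and RXRA below 0 in both.

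Chicken germ cells from the adherent fraction, from DIV6 and from the line have 1 library each, so they are given as log2 ratios against the mean of both non-adherent DIV3 libraries, with no test and no replicate. In adherent germ cells (54 cells) the 10 highest ratios included ACTA2, FN1, THBS1, KRT18 and KRT7. ACTA2 stood at 430 CPM (Poisson interval 405 to 456) against 5.67 and 69.2 at DIV3, FN1, fibronectin, at 616 CPM (586 to 647) against 37.7 and 87.4, and THBS1 at 345 CPM (322 to 369) against 15.1 and 42.4. The median of 13 extracellular matrix genes was 2.2, above all 10000 random lists, in a library with 60.0% smooth-muscle-like cells. DAZL stood at 1097 CPM against 1108 and 1151, NANOG at 484 CPM against 448 and 578, DDX4 at 178 CPM (162 to 196) against 438 and 246, and POU5F3 at 160 CPM against 486 and 84.6.

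At DIV6 chicken germ cells had lower levels of cell cycle genes and little difference in meiosis genes. Their log2 CPM correlated with the DIV3 mean at r = 0.9616 over 4199 genes, which are not independent replicates. Both DIV3 libraries correlated with each other at r = 0.9206 over 3938 genes, with 39 genes more than 2-fold higher and 82 lower in replicate 1. These r values are not alike, since a mean of 2 libraries varies less than 1 library and the gene sets differ. Outside the range of both DIV3 libraries and more than 2-fold from their mean lay 28 genes above and 4 below. That rule is stricter than the 2-fold count between both DIV3 libraries. MKI67 stood at 102 CPM (99.0 to 106) against 241 and 150, NUF2, a kinetochore protein, at 118 CPM (115 to 122) against 295 and 180, and KIF11, a spindle motor, at 60.9 CPM (58.3 to 63.4) against 158 and 89.0. The median log2 ratio of 27 cell cycle genes was -0.38, below all random lists, but both DIV3 libraries differed in that median by 0.38 as well. Of these genes 20 were lower than both DIV3 libraries and 1 higher. Over the 4199 genes, 1430 lay below both and 1143 above. The median of 12 meiosis genes was -0.11 (percentile 13.7). AVD, avidin, stood at 140 CPM against 0.529 and 37.1 and COX5A, a respiratory chain subunit, at 246 CPM (241 to 251) against 78.7 and 56.2. DAZL was at 1127 CPM, DDX4 at 268 (log2 ratio -0.35), NANOG at 716 (0.48) and POU5F3 at 260 (-0.14).

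In the chicken line at DIV150, DAZL and NANOG lay below both DIV3 libraries, DDX4 and POU5F3 lay between them, and stress and PGC identity genes were mostly lower. DAZL stood at 724 CPM (log2 ratio -0.64), DDX4 at 283 (-0.27) against 438 and 246, NANOG at 300.5 (-0.77) and POU5F3 at 165 (-0.79) against 486 and 84.6, and the median of 20 germline genes was -0.22 (percentile 42.5). The median of the integrated and ER stress list was -0.67 (percentile 0.01), with 14 of 17 members lower than both DIV3 libraries, that of pluripotency and PGC identity -0.54 (percentile 0.33; 13 of 19 lower), and that of oxidative phosphorylation 0.17 (percentile 98.5; 17 of 26 higher). RSPO3 stood at 979 CPM (973 to 985) against 168 and 356, the avian embryonic gene ERNI at 868 CPM against 129 and 290, DPY30, a histone methylation cofactor, at 769 CPM against 206 and 190, and FABP7, a fatty-acid-binding protein, at 288 CPM against 60.5 and 35.9. CYP26C1, a retinoic-acid-degrading enzyme, stood at 9.01 CPM (8.46 to 9.58) against 103 and 95.7, and NFIA at 3.16 CPM against 40.8 and 68.5. HINTW, which lies on the female-specific W chromosome, stood at 0.0176 CPM (0.00213 to 0.0635) against 723 and 2108, in a line derived from a male and pools of unsexed embryos. Erythroid (median -6.18) and smooth muscle (-3.11) markers were lower in a library with no cell of either class. The line differs from the DIV3 libraries in derivation, feeder layer, freezing and time, and none of these can be told apart.

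Mouse feeder cells were a small part of the line's library. UMIs mapped to the mouse genome made up 2.24% of all UMIs. Of 9800 barcodes called in either genome, 36 were mouse cells, 0.367% (0.257 to 0.508), with a median of 5325.5 mouse UMIs. These cells had Vim at 3278 CPM, Fn1 at 1044 CPM and Col1a2 at 314 CPM, while other fibroblast genes were near or at 0, Col3a1 with 7 UMIs, Postn and Lum with 1 each and Dcn with 0. They had 0 UMIs of the leukocyte gene Ptprc and the germ-cell genes Ddx4 and Pou5f1. Of 7270 chicken germ cells, 4563 shared a barcode with the mouse table, with a median of 2.72% mouse UMIs and a highest share of 34.9%. Of all 3133002 UMIs mapped to mouse, 2995601 lay on barcodes also called in the chicken table, and whether these came from feeder cells was not tested. The 32 mouse barcodes absent from the chicken table had their chicken UMIs counted as 0.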

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

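The tests of leukocyte RNA and of read number at DIV8, of surrounding RNA in adherent germ cells and of culture batches, and the comparison of day changes between species, were chosen only after the result was seen, as was the count of other splits in the species comparison. Between DIV3 and DIV6, 15 of 11807 genes changed differently in zebra finch than in chicken germ cells by the interaction term of edgeR (6 non-adherent libraries; 10 with a higher and 5 with a lower change in zebra finch), with 1341 genes at an unadjusted p under 0.05 and 195 by DESeq2. Each species has 1 library at DIV6, so every gene p here rests on the spread of the DIV3 pairs. It assumes that DIV6 libraries vary like them. The list p builds on the same gene values, but with the preset correlation it measures the spread between genes and not between libraries. A difference between these 2 DIV6 samples alone cannot be told from one between species. The meiosis list changed by a mean of 1.77 more on the log2 scale in zebra finch (camera adjusted p = 6.82e-08; adjusted p = 0.643 with an estimated correlation), with 9 of 19 members higher when adjusted over the list alone. Macrophage and leukocyte markers (mean -3.96, camera adjusted p = 0.00848; adjusted p = 0.785 with an estimated correlation) and the cell cycle list (mean -0.45, camera adjusted p = 0.00848; adjusted p = 0.785 with an estimated correlation) had lower changes in zebra finch. Macrophage-like cells went from 20.4% and 21.3% to 3.86% of non-adherent zebra finch cells and from 0.154% and 2.33% to 17.72% of chicken cells. The macrophage call was lost without zebra finch DIV3 replicate 2 (adjusted p = 0.0721) and the cell cycle call without chicken DIV3 replicate 2 (adjusted p = 0.275). TEX12 differed by 6.30 ± 0.93 (SE; adjusted p = 0.0471), going from 0.177 and 0.375 to 20.03 CPM in zebra finch and from 0.696 and 1.79 to 1.17 CPM in chicken. CCDC73 differed by 4.50 ± 0.64 (adjusted p = 0.0413), SPDYA, an activator of cyclin-dependent kinases in meiosis, by 4.03 ± 0.56 (adjusted p = 0.0375) and ENO4 by 3.89 ± 0.60 (adjusted p = 0.0472). In the other direction, FGFBP3, which releases FGFs from the matrix, differed by -3.56 ± 0.46 (adjusted p = 0.0343), CBLN2 by -2.98 ± 0.44, CXXC5 by -2.52 ± 0.38 and GFRA1, a GDNF receptor, by -2.41 ± 0.37. GPR149 had counts of 0 in both zebra finch DIV3 libraries and LRRTM4 counts of 3 and 2, so no fold is given for them. Germ cells by DDX4 and DAZL UMIs gave 0 such genes, with differences of similar size (TEX12 5.95, CCDC73 4.39, FGFBP3 -3.76, each at adjusted p = 0.430). Leaving out chicken DIV3 replicate 2 gave 1199 genes and replicate 1 gave 588, with all 15 among them both times. Leaving out zebra finch DIV3 replicate 1 gave 24 and replicate 2 gave 18, with 13 and 10 of the 15 among them. DAZL (-0.09 ± 0.44) and DDX4 (1.10 ± 0.51, adjusted p = 0.453) did not differ past the threshold.

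The bulk DIV8 library lay farthest from the line of day fitted to the other 11, with a root mean square residual of 2.24 log2 units against 0.549 to 1.37 elsewhere. It is not a library of fewer reads, since its 55.747 M reads lie inside the range of 53.519 to 66.937 M, and its 10 leading genes held 23.1% of reads against at most 12.1%, which met what was written beforehand for a few genes taking most counts. In a comparison made after these values were seen, leading genes alone would lower all other genes alike, yet macrophage-specific and germ-cell-specific genes stood 3.73 log2 units apart, which argues against that share as the whole cause. The 131 genes that single-cell macrophage-like cells hold at 10 or more times the level of every other named class had a median residual of 2.536 (interquartile range 1.99 to 2.81), while 26 germ-cell-specific genes stood at -1.19 (-1.49 to -0.847), so a larger share of leukocyte RNA may be part of the difference. Kidney markers stood higher at DIV8 too (mean log2 CPM 5.06), dissection and culture of that sample are not described apart from the others, and with 1 library at DIV8 no biological explanation was tested.

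In adherent zebra finch germ cells, 402 genes led by matrix and contractile genes were higher. RNA of surrounding somatic cells in the same droplets may account for much of this: of the higher genes outside the lists that set the free RNA level, 90.67% at DIV3 and 93.3% at DIV6 had an excess of at most 2 times the level set by matrix and mesenchyme genes, whose level in germ cells was 10.1% and 13.9% of that in the other cells of the adherent libraries (lower quartile) against 1.56% to 4.49% in suspended ones. Doublets of a germ cell and a somatic cell are argued against as the main source, since the median germ cell carried 0.9044 of the mean share of these transcripts at DIV3 and 0.9392 at DIV6, whereas a few mixed cells would leave the median far lower. After subtraction of the other cells' profile 1 gene stayed past the threshold, but folds then ran from -10.98 to 12.23 because counts reached 0, so the loss of calls by itself decides nothing. A change in germ cells that attach stays open and was not tested apart from this RNA.

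Meiosis genes were higher at DIV6 than at DIV3 in zebra finch germ cells. A difference between culture batches A and B is argued against as the whole cause, since the list stayed higher among batch B libraries alone. There its camera adjusted p was 1.718e-07, and over all 5 libraries it was 0.593 with an estimated correlation. The batch B fit has 1 library per fraction and day, all from 1 pool. Its list p therefore rests on the spread between genes and not between cultures. After subtraction of surrounding RNA 17 of the 19 genes that rose stayed past the threshold, with a median log2 fold change of 1.81 against 1.82 before. In suspended libraries the share subtracted was only 1.56% to 4.49% of the other cells' profile, set there by 2 to 6 genes. Subtraction of so small a share could change these folds little, so this test does not decide on surrounding RNA. Onset of a meiotic programme during culture was not contradicted by the batch test. It stays a hypothesis, found and tested on the same libraries, with all DIV6 cells from 1 pool. A change in which germ cells survive or stay in suspension was not tested.

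Of the 10 splits of the 6 libraries of the species comparison into 3 and 3, 1, the real one, gave as many genes as the 8176 found, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.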

How the results depend on the processing

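Chosen only after results had been seen were the leukocyte covariate, the crossed replicate block, the subtraction of the other cells' profile, the sums over named classes, the alternatives for lists in the single-cell comparisons and all of those for the day change between species. Across alternatives, single named genes kept their side of the threshold (and direction where past it) or, untested, stayed within their spread in 3171 values. They were no longer past it in 112 and newly past it in 7, and changed sign with at least 1 fit past it in 5. Where untested, they moved by more than their spread in 54. For lists these numbers were 1559, 99, 97, 6 and 9. A change of sign with neither fit past the threshold counts among the values kept. Counts of genes and the other main values stayed within 1.5 times, or within their spread, in 330, lost a call in 2 and moved further in 87. With 1 library left in a group, the spread is borrowed from the other groups, which assumes that it varies like them. Depth sets limits in the adherent germ-cell sums (90 and 81 cells in zebra finch, 54 in chicken) and in chicken DIV3 replicate 1 (36571182 UMIs), and genes under the low-count filter were not tested. Except where a cause is stated, the cause was not tested.

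The bulk day trend called between 3617 (without DIV2; 3595 among the 5205) and 7875 (without DIV8; 5198 among them) genes, with 1702 to 4033 rising. It gave 4019 genes with a block of replicate number and 4397 with the DIV10 numbers crossed, and the deviations of replicates 1 and 2 at DIV9 and DIV10 correlated across genes with r = -0.382 (genes are not independent replicates), so the numbers do not show a pairing. DESeq2 gave 6669, limma-voom 5407, log2 of day 4763 and the spline 4933. Of the bulk lists, 7 passed camera with the preset correlation, 0 with an estimated correlation (which widens the null by construction), 15 with fry, 4 with log2 of day, and 3 (without DIV8) to 10 (without DIV7) with 1 library left out. With the leukocyte marker mean as a covariate, the macrophage and leukocyte list stood at 0.0004404 (adjusted p = 0.917) with the direction of the test turned, near 0 because its own mean is in the model, and 7017 genes passed, 4342 of them among the 5205.

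Germ-cell shares depended on which cells entered. With at least 1000 genes per cell they were 90.4% in the line, 15.44% and 15.89% in chicken non-adherent DIV3 replicates 1 and 2, 32.37% in chicken DIV6, 69.03% and 69.44% in zebra finch non-adherent DIV3 replicates 1 and 2 and 86.73% in zebra finch non-adherent DIV6. Calling germ cells by DDX4 and DAZL UMIs gave 83.37%, 17.95%, 21.68%, 27.73%, 67.71%, 68.88% and 78.22% in the same order. Keeping doublets gave 83.49% in the line and 4.482% in chicken DIV3 replicate 1, and moved the median log2 ratio of the glycolysis list to 0.1513 in chicken adherent germ cells and to -0.36 in the line. Under both, shares in each non-adherent group stayed higher in zebra finch than in chicken. Mouse cells numbered 24 when 90% of UMIs had to be mouse.

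In zebra finch germ cells by day, counts without 1 library ran from 872 (without non-adherent DIV6) to 6358 (without non-adherent DIV3 replicate 1), with 555 to 3373 higher and 317 to 2985 lower. HBE1 stood at 0.20143 with DESeq2 (adjusted p = 0.971) and ran from -4.3748 to 10.283 without 1 library, and HBAD from -4.8608 to 0.0, where without non-adherent DIV6 the day term rests on adherent libraries at 0 or near 0 counts. By fraction, subtraction of the other cells' profile left 1 gene (1 higher and 0 lower), with COL1A2 at -10.977 and CSF3R at 3.562, sums that subtraction had taken to or near 0. At least 1 count in every library left 9 lower genes, since genes absent from the small adherent sums go untested. Calling germ cells by DDX4 and DAZL UMIs gave 53 lower genes. Counts without 1 library ran from 346 to 671, with 13 to 129 lower. The direction for the cholesterol list turned with fry (mean -0.0672) and under no other alternative tried.

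In the other zebra finch cells, counts by fraction without 1 library ran from 3461 to 5827, with 1798 to 3062 higher and 1663 to 2765 lower. By day, edgeR called 1 gene, DESeq2 390 (179 higher and 211 lower), named classes alone 2 (1 higher), and 0 were called (0 lower) with at least 1 count in every library, with at least 1000 genes per cell and with doublets kept. Without 1 library the count ran from 1 to 1260, with 0 to 529 higher and 1 to 731 lower. Lists by day whose direction turned, each without non-adherent DIV6, were germline (-0.04389 to 1.202), germ-cell markers (-0.1352 to 1.603), oxidative phosphorylation (-0.5126 to 0.04242) and pluripotency and PGC identity (-0.6975 to 0.6267).

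The species comparison gave 8070 genes with culture batch as a block. Deviations of batches A and B at DIV3 correlated across genes between the species with r = 0.145, and genes are not independent replicates. The day change between species called 15 genes with edgeR, 195 with DESeq2 (98 higher and 97 lower), 34 with doublets kept (21 and 13), 8 with at least 1000 genes per cell (6 and 2), and 0 (0 and 0) both with at least 1 count in every library and with germ cells by DDX4 and DAZL UMIs. Without 1 library the count ran from 18 to 1199, with 11 to 504 higher and 7 to 695 lower. The GRC paralogue list in zebra finch had a mean log2 fold change of 0.9093, which no longer passed with an estimated correlation (p = 0.189), and without 1 library it ran from 0.7574 (p = 0.058, without adherent DIV3) to 1.063.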

Other observations

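The test of the difference in GRC paralogues between species was set down before its result was seen, and the comparison of bulk with single-cell changes, the thinned shares of cells and the counts of mouse UMIs were chosen only after other results had been seen. Bulk slopes over 10 days and day changes in single-cell germ cells went together across 16109 genes measured in both (Pearson r = 0.572, Spearman rho = 0.494; genes are not independent replicates). Genes past the threshold in both numbered 1165 higher, against 398 for independent lists, and 779 lower, against 308, while 39 and 78 went opposite ways. Without the DIV8 library r was 0.604.

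Each cell with at least 5000 UMIs was thinned to 5000, and shallower cells were left out. At non-adherent DIV6 these were 114 of 317 macrophage-like and 162 of 6306 germ cells in zebra finch. In chicken they were 536 of 763 and 2 of 828, so the macrophage-like shares there describe the deeper cells only. A UMI of STRA8 was found in 1.8% and 2.25% of zebra finch non-adherent germ cells at DIV3 and in 19.65% (95% Clopper-Pearson interval 18.7 to 20.7) at DIV6. In macrophage-like cells of the same libraries, which should lack STRA8, the share was 1.38% and 2.11% at DIV3, so the DIV3 shares in germ cells are at background, and 6.40% (3.45 to 10.7) at DIV6. TEX12 was found in 0.0916% and 0.175% of germ cells at DIV3 and 5.65% at DIV6, against 0% and 0% (intervals up to 0.362% and 0.324%) and 1.48% (0.306 to 4.26) of macrophage-like cells. SYCP3, a lateral element of the synaptonemal complex, was found in 10.2% and 8.91% at DIV3 and 21.5% at DIV6, against 1.38%, 1.14% and 8.37%. KIT went the other way, 3.48% and 4.03% at DIV3 and 0.570% at DIV6, against 0.0984%, 0.528% and 0% (interval up to 1.80%) of macrophage-like cells. In chicken germ cells STRA8 was found in 1.30% and 1.37% at DIV3, 3.15% (2.07 to 4.58) at DIV6 and 1.42% of the line. In DIV6 macrophage-like cells its share was 0.441% (0.0112 to 2.43). KIT was found in 26.5% and 30.5% at DIV3, 19% at DIV6 and 37.0% of the line, against 1.76% of DIV6 macrophage-like cells. SYCP3 and TEX12 were found in a smaller share of chicken germ cells than of macrophage-like cells. For SYCP3 the shares were 5.769% against 20.48% in non-adherent DIV3 replicate 2 and 5.811% against 12.33% at non-adherent DIV6. For TEX12 they were 1.099% against 4.819% and 0.6053% against 2.203% in the same libraries, with overlapping intervals.

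Of 18 GRC paralogues 10 were higher and 3 lower in zebra finch germ cells than in the other cells, with the list call lost with an estimated correlation (p = 0.189). A hypothesis is that the log2 ratio of germ cells to other cells is higher in zebra finch, which has the chromosome, than in chicken, which lacks it. The interaction of species and class gave a camera p of 0.1256 (p = 0.213 with an estimated correlation), with a mean difference of 0.48 log2 units in the direction of the hypothesis, so the test left it open. Without 1 library the p ran from 0.070 to 0.273. Single genes went both ways, with a ratio higher in zebra finch past the threshold for VEGFA (1.91), PUF60 (1.55), ROBO1 (1.48) and PRPSAP1 (1.36) and lower for GBE1 (-0.95) and PIM3 (-0.66). For VEGFA this came from chicken, where it was lower in germ cells (-2.41) than in the other cells, against -0.49 in zebra finch, and PUF60 stood at 0.80 in zebra finch and -0.78 in chicken.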
